A study of Homo sapiens with 2 samples.

How the data were processed

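RNA from the parental line HL60 and from the cytarabine-resistant line R-HL60 was hybridised to Agilent one-colour arrays, 1 array per line. Per the labels' protocols, total RNA was taken with TRIzol, labelled with Cy3 by a low-input amplification kit and read as 1 colour. Per the submitters' processing notes, Agilent Feature Extraction 10.7.3.1 was used. The deposited files of each array hold 1 linear intensity per probe and a gene name, without probe identifiers, background values or detection flags; which scanner column they hold and how background was treated is not given in the sources used here. The authors also deposited a table of normalized intensities for both arrays. Its sorted values lay within 1.06% of the mean of both arrays at every rank, as quantile normalization gives, but its method is not given in the sources used here; it was used as an alternative.

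Each signal was taken to log2 and the array's own 75th percentile was subtracted. As no detection flags were at hand, the floor was the array's median signal. A gene with several probes was represented by the probe with the highest mean over both arrays. Genes above the floor on both arrays have a measured difference. Genes above it on 1 array have a bound, written as at least N-fold and computed against the higher of the floor and the gene's own value, and genes below it on both have none. A bound under 2-fold was not counted as past 2-fold, although the difference itself can be larger. The 43317 names in the files were matched to a gene table of assembly GRCh38.p14: 21081 were current symbols, 1567 an older symbol of 1 gene, which was updated, 57 an older symbol of several genes and 20612 were not matched; the last 2 kinds kept the file's name. The assembly behind the array design is not given in the sources used here, so the table served for names and for the order of neighbouring genes only, and no coordinates are given.

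With 1 array per line no test, standard error or p-value was computed. Genes were counted when the log2 difference (resistant minus parental) reached 2-fold. The precision is limited by the number of arrays; the only repeated measurement was that of different probes for a gene, whose spread was computed in bins of brightness. Before the data were examined, 35 gene lists were fixed. The median difference of each list over its members above the floor on at least 1 array was placed among 10000 random lists of the same size, matched in 20 bins of mean brightness, as a description of these arrays. Some genes belong to several lists, such as ICAM1 and BIRC3.

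Named genes followed a rule fixed at the same time. It took the 12 largest differences in each direction among genes above the floor on both arrays whose measured probes all pointed the same way. A gene without a further measured probe met this condition by definition. Of the genes taken, only CPXM1, IGLL1, PRUNE2 and PTPRS had a further measured probe, so for the others agreement between probes was not tested. The rule also took the 6 largest bounds in each direction, and clone and predicted-transcript names were left out throughout. From each list the rule took up to 4 members past 2-fold, or otherwise the member with the largest difference. It added 20 genes of cytarabine handling and of the HL60 line whatever their value. Other list members and genes of the chromosome 18 run were named after their values were seen.

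Alternatives were quantile normalization, a median shift, loess by brightness, the authors' table, an offset of 50 units, floors at the 40th and 60th percentile or none, genes above the floor on both arrays, the mean of all probes, thresholds of 1.5-fold and 3-fold, agreement of all probes, unmatched random lists and list means. A value without a test was called moved when it differed by more than the probe-to-probe SD of 0.17, and a count when it differed by more than 1.5 times. For runs of neighbouring genes, means over 25 consecutive genes above the floor on both arrays were compared with those of 1000 random gene orders. The steps were tested on simulated data for resistant against parental with 43270 genes and the probe-to-probe error of each brightness bin. All 100 genes changed by 2.5-fold and all 100 changed by 4-fold were recovered past 2-fold, and 0 of 23016 unchanged genes passed. The changed genes were placed well above the floor, and no variation between cultures or arrays was simulated. This recovery therefore checks the steps and does not give the error rate of the real comparison. A list shifted by 0.3 on the log2 scale came out at percentile 100, with 2 of the other 34 lists outside the central 95%. A run of 50 neighbours shifted by 0.3 was found. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.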

Results

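Gene expression was measured in the parental human leukaemia line HL60 and in R-HL60, a line derived from it by continuous growth in increasing concentrations of cytarabine. HL60 is an acute myeloid leukaemia line of promyelocytic character, and cytarabine is a deoxycytidine analogue that stops DNA synthesis once it is phosphorylated in the cell. Each line was represented by 1 Agilent one-colour array of 58201 probes. The median signal was 30.7 on the parental and 32.8 on the resistant array, and the 75th percentile was 292 and 294. Of 43270 genes and transcripts, 21839 lay above the array's median, used as the floor, on both arrays, 1692 on 1 array only and 19739 on neither. There were no replicates, so no difference has a test between cultures, and the array and the cell line cannot be told apart.

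The comparison asked which genes differed in expression between the cytarabine-resistant line and its parent. The resistant array carried far higher signals for CYLD, a deubiquitinase that limits NF-kB signalling, for the chemokine CXCL10, for the apoptosis inhibitor BIRC3 and for CD70, the ligand of CD27. Signals were far lower for CLC, which encodes the Charcot-Leyden crystal protein, for the receptor tyrosine kinase FGFR1 and for the cancer-testis antigen gene XAGE1B. In all, 185 genes or transcripts were at least 2-fold higher and 70 at least 2-fold lower, together 1.08% of the 23531 above the floor on at least 1 array. Of the higher ones 96 were protein coding, 22 belonged to other named classes and 67 had no entry in the reference table, against 46, 10 and 14 of the lower ones. At least 8-fold differences were found for 11 higher and 4 lower genes.

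The remaining genes were close to equal on both arrays. Over the 21839 genes above the floor on both, the log2 difference (resistant minus parental) had a median of -0.03 and an SD of 0.29, 95.6% of genes lay within 1.5-fold, and Pearson's r across genes, which are not independent replicates, was 0.996. Different probes for a gene gave log2 differences with a probe-to-probe SD of 0.17 over 4215 genes, from 0.27 for the dimmest to 0.08 for the brightest. This error leaves out the spread between cultures and between arrays. Of 19 genes with several measured probes and the brightest past 2-fold, every probe pointed the same way in 11 and passed 2-fold in 3.

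**Figure D1:**
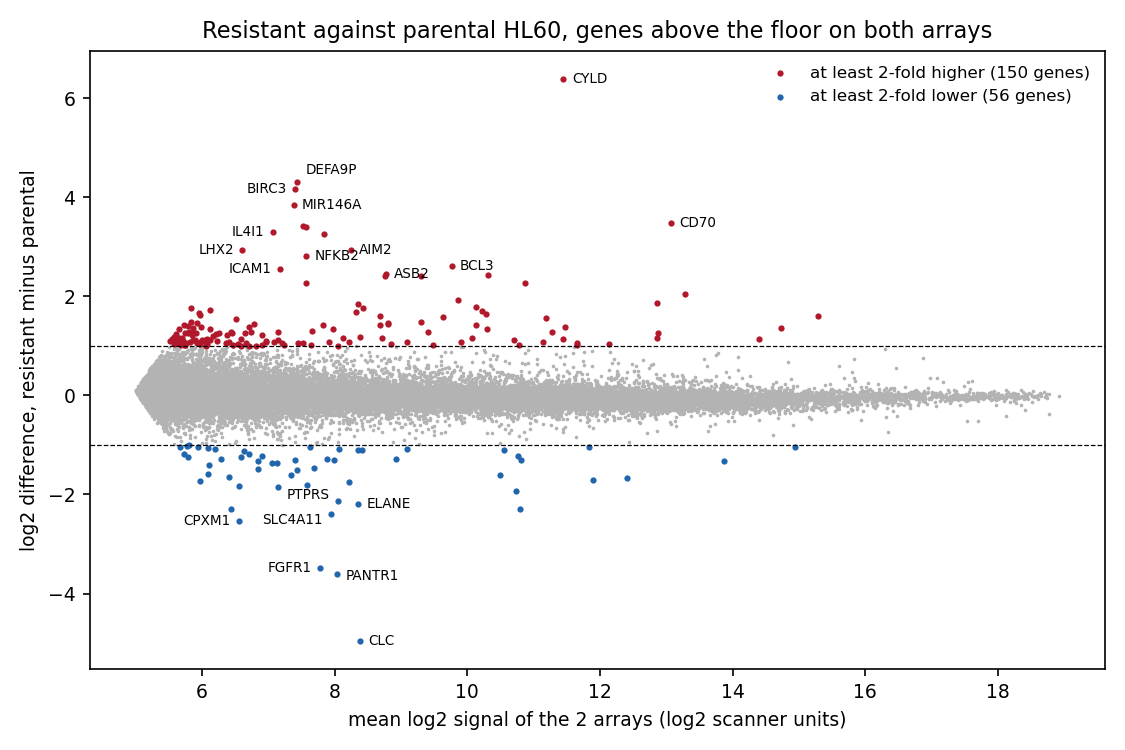
Log2 difference of the resistant minus the parental array (vertical axis) against the mean log2 signal of both arrays (horizontal axis), 1 point per gene above the floor on both arrays. Dashed lines mark 2-fold; 150 genes lie above them in red and 56 below them in blue, with CYLD at 6.39 and CLC at -4.95 as the extremes; labels mark those of the 12 genes named per direction that were past 4-fold.

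NF-kB feedback and target genes were the list that stood furthest apart. Of its 16 measured members, 8 were at least 2-fold higher on the resistant array, none was 2-fold lower and 14 had a difference above 0. BIRC3 went from a signal of 39.8 to 722 (log2 difference 4.17), NFKB2, which encodes the p100 precursor of the non-canonical pathway, from 71.4 to 505 (7.04-fold), BCL3 from 351 to 2151 (6.09-fold) and the adhesion molecule ICAM1 from 59.3 to 352 (5.90-fold). The other members past 2-fold, named after their values were seen with log2 differences in parentheses, were TNFAIP3 (2.44), RELB (2.05), CD83 (1.57) and the inhibitor NFKBIA (1.25). With an offset of 50 units, which shrinks folds that rest on dim signals, BIRC3 was 8.56-fold, NFKB2 4.55-fold and ICAM1 3.66-fold higher. RELA and SOD2 were nearly equal on both arrays, at -0.08 and -0.02. The list median of 1.06 lay above all 10000 random lists of the same size and brightness, whose central 95% ran from -0.14 to 0.05. This percentile describes these 2 arrays only. With genes past 2-fold left out, a setting chosen after seeing the data, the median of the other members was 0.32, still above all random lists.

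Among the genes named by the size of their difference, CYLD had the largest difference measured on both arrays, from 305 to 25699 (83.9-fold). CYLD and the other genes of this paragraph that were measured on both arrays rested on 1 probe each. So did BIRC3, NFKB2, BCL3 and ICAM1. CD70 went from 2581 to 28901 (11.1-fold), the amino acid oxidase IL4I1 was 9.82-fold higher, the cytosolic DNA sensor AIM2 was 7.65-fold higher and the ubiquitin ligase subunit ASB2 was 5.45-fold higher. The precursor gene named MIR146A in the files was 14.3-fold higher, from 43.9 to 632; the mature microRNA was not measured by these probes. LHX2, a LIM homeobox transcription factor, was 7.64-fold higher. DEFA9P, an alpha-defensin pseudogene, was 19.7-fold higher, but its probe could also bind transcripts of related defensin genes. Among genes above the floor on the resistant array only, MIR124-1HG was at least 6.67-fold and CLPSL1 at least 4.32-fold higher. The bound for CLPSL1 was 0.66 on the log2 scale in the mean of all probes. EXOC3L4 was at least 3.08-fold, KLK3 at least 2.79-fold and NALF2 at least 2.78-fold higher, bounds that fell under 2-fold with the offset. Several of these folds rest on dim parental signals and were smaller with the offset of 50 units, at 9.19-fold for DEFA9P, 7.23-fold for MIR146A, 5.06-fold for IL4I1, 3.74-fold for LHX2, at least 3.16-fold for MIR124-1HG and at least 2.26-fold for CLPSL1.

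Cytokine and chemokine genes were higher as a list, with a median of 0.27 over 19 measured members that lay above all random lists. CXCL10, an interferon-inducible chemokine, was at least 64.5-fold higher, from below the floor on the parental array to 1991, or at least 25.2-fold with the offset. CCL5 was 3.65-fold higher at 14251 and CCL2 was 2.42-fold higher at 3869, and the other 14 members measured on both arrays were within 2-fold. IL6 and IL10, above the floor on the resistant array only, had bounds of 0.51 and 0.22 on the log2 scale, which leave larger differences open. TNF went the other way, with a log2 difference of -0.94 that did not reach 2-fold. Interferon-stimulated genes had a median of 0.17, again above all random lists, with 2 of 33 past 2-fold: IFIH1, a sensor of double-stranded RNA, was 3.45-fold and OAS3 2.55-fold higher. The list did not move as a block, since 11 members had differences below 0, among them IFIT1 (-0.48), IFIT2 (-0.56) and IFIT3 (-0.44).

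Antigen presentation genes had a median of 0.32 over 18 members, 16 of them above 0, and this too lay above all random lists. PSMB9, an immunoproteasome subunit, was 2.20-fold higher, and HLA-F was 2.20-fold higher on its brighter probe. The mean of the HLA-F probes was 0.30 on the log2 scale. Its other probe was not above the floor on both arrays, so it is not a second measurement that disagrees. The class I genes HLA-B and HLA-C had log2 differences of 0.74 and 0.94, while HLA-DQB1 of class II was at -0.49. HLA probes can bind related HLA transcripts, so values of single HLA genes are uncertain. Adhesion and migration genes had a median of 0.10 at percentile 99.97, with ICAM1 5.90-fold and VCAM1 at least 2.03-fold higher and the other 23 within 2-fold. VCAM1 was above the floor on the resistant array only, and its bound on the log2 scale was 0.47 with the offset.

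The azurophil granule list lay below and the neutrophil maturation list above their random lists. Of 17 measured members of the azurophil list, 4 were at least 2-fold lower on the resistant array and none was 2-fold higher. Of these 4, ELANE and PRSS57 encode serine proteases of azurophil granules, whereas CLC and PRG2 encode proteins of eosinophils, the Charcot-Leyden crystal protein and major basic protein. CLC went from 1852 to 60.1 (log2 difference -4.95, or -4.12 with the offset), ELANE from 700 to 153 (4.59-fold lower), PRG2 was 3.16-fold lower and PRSS57 was 2.51-fold lower. The myeloperoxidase gene MPO, among the brightest genes at 309491 and 285746, differed by -0.12. The list median was -0.15, at percentile 0.57 of its random lists. It was -0.14 at percentile 0.80 over 14 members with the measured eosinophil genes CLC, PRG2 and RNASE2 left out, a setting chosen after seeing the data. The full list lay outside the central 95% in 13 of 14 other settings, the exception being the removal of genes past 2-fold. Of 21 neutrophil maturation genes, 3 were past 2-fold higher, namely CYBB, a subunit of the phagocyte oxidase (4.79-fold), the gelatinase gene MMP9 (3.27-fold) and S100A9 (2.68-fold), and 18 were above 0, with a median of 0.28 above all random lists. Monocyte and macrophage genes had a median of 0.09 at percentile 92.5, with none of 26 known to be past 2-fold; 23 of them were measured on both arrays.

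Other genes with much lower signals on the resistant array came from several families. FGFR1 went from 731 to 66.0 (11.1-fold lower), the membrane transporter gene SLC4A11 was 5.26-fold lower, the receptor phosphatase gene PTPRS was 4.40-fold lower and IGLL1, which encodes a surrogate immunoglobulin light chain component, was 3.82-fold lower. A further probe of IGLL1 gave -2.81 and one of PTPRS gave -0.71 on the log2 scale. FGFR1 and SLC4A11 had no other measured probe. The long non-coding RNA gene PANTR1 was 12.1-fold lower on its brighter probe, and -0.96 on the log2 scale in the setting that moved it most. Its other probe was not above the floor on both arrays. A further probe of CPXM1, which was 5.76-fold lower on its brighter probe, gave -0.93. PLA2G3 was 3.62-fold, AEBP1 3.52-fold and CARD10 3.36-fold lower. PRUNE2 was 3.56-fold lower on its brightest probe, but another measured probe gave -0.12 on the log2 scale. Among genes above the floor on the parental array only, XAGE1B was at least 48.5-fold lower, the transcription factor MITF at least 6.46-fold and LY6K at least 4.46-fold. TCAM1P was at least 3.16-fold, DLG3 at least 2.98-fold and MIR3667HG at least 2.37-fold lower, bounds that fell under 2-fold with the offset. XAGE1B belongs to a family of near-identical copies, so its probe does not separate them. With the offset, PANTR1 was 7.69-fold, FGFR1 6.77-fold and CPXM1 3.09-fold lower, and the bounds were 19.8-fold for XAGE1B, 3.16-fold for MITF and 2.37-fold for LY6K.

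**Figure D2:**
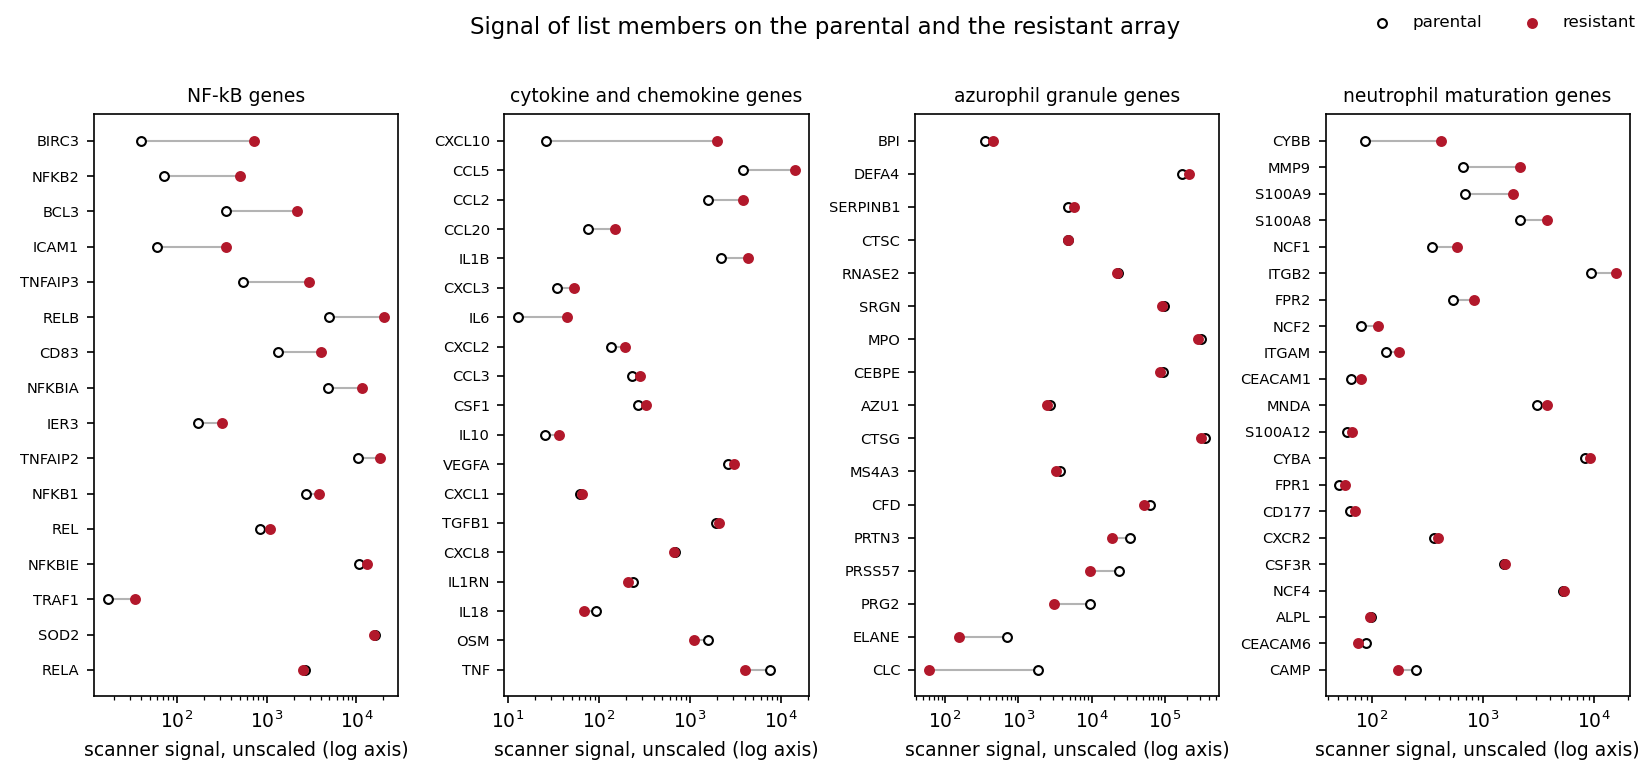
Signal of each measured member of 4 gene lists on the parental array (open circles) and the resistant array (filled circles), on a log axis in unscaled scanner units, sorted by difference. BIRC3, CXCL10 and CYBB lead the lists with higher members, and CLC and ELANE lie furthest to the lower side within the azurophil granule list.

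Transcript signals of most measured genes of cytarabine uptake, activation and inactivation were nearly equal on both arrays. Enzyme activity and gene sequence were not measured. DCK, the kinase that makes cytarabine monophosphate, differed by -0.01, the nucleoside transporter SLC29A1 by 0.01, cytidine deaminase CDA by -0.01 and SAMHD1, which hydrolyses cytarabine triphosphate, by -0.16. The deaminase DCTD differed by 0.29, the nucleotidase NT5C2 by -0.15 and the ribonucleotide reductase subunits RRM1 and RRM2 by -0.06 and 0.02. None of the 30 members of this list above the floor was past 2-fold, ADA having only a bound of -0.26, and the largest difference was that of the transporter SLC28A1 at -0.57. The dim genes CDA and SLC28A1 lie in brightness bins with probe-to-probe SDs of 0.22 and 0.27. The list median of -0.06 lay at percentile 26.5. The ABC drug efflux list had a median of 0.01 over 11 members at percentile 66.9, with ABCC1 at 0.07, ABCC4 at -0.07 and ABCG2 at 0.06. Its members ran from ABCC6 at -0.40 to MVP at 0.31. MVP and LRP1 are on this list but are not ABC transporter genes, and the highest ABC gene was ABCC2 at 0.24. ABCB1 was below the floor on both arrays. SLFN11, which stalls replication under DNA damage, was at -0.42 and was the largest difference among 48 checkpoint and repair genes, whose median was -0.05 at percentile 68.7.

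Apoptosis genes differed little apart from a few members. BCL2, BCL2L1 and MCL1 had log2 differences of 0.20, 0.02 and -0.12, and of 10 measured anti-apoptotic genes only BIRC3 was past 2-fold (list median 0.03, percentile 93.8). Among 28 pro-apoptotic genes BMF was 2.23-fold and BBC3 2.09-fold higher, with PMAIP1 at 0.99, and the list median of 0.02 lay at percentile 99.2. BMF was close to the floor, and this list was outside the central 95% in only 8 of 14 other settings. Among 28 genes of the unfolded protein and integrated stress response, DDIT3 was 2.25-fold and ATF3 2.03-fold higher. Further probes of ATF3 ranged from -0.29 to 0.89, and the chaperone gene HSPA5 was at -0.44. That list's median was 0.00 at percentile 98.4, outside in 10 of 14 other settings.

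The MYC target and cholesterol lists had medians slightly below those of their random lists. All 30 MYC list members had differences below 0, but random lists of this brightness also had a median of -0.05, and members such as LDHA (-0.01) and NPM1 (-0.04) lay above that level. The list median was -0.18, below all random lists, with none past 2-fold and MYC itself at -0.42. All 25 cholesterol genes were below 0, none past 2-fold, where random lists had a median of -0.06, with a median of -0.18 at percentile 0.02 and INSIG1 at -0.51 as the largest difference. Histone genes had a median of 0.17 and G2/M genes a median of 0.06, both above all random lists, without a member past 2-fold; H1-2 was at 0.38 and PTTG1 at 0.35. The G2/M list was outside the central 95% in 13 of 14 other settings. Replication genes of S phase had a median of -0.11 at percentile 2.97 and lay inside, but 6 of 14 other settings put them outside.

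**Figure D3:**
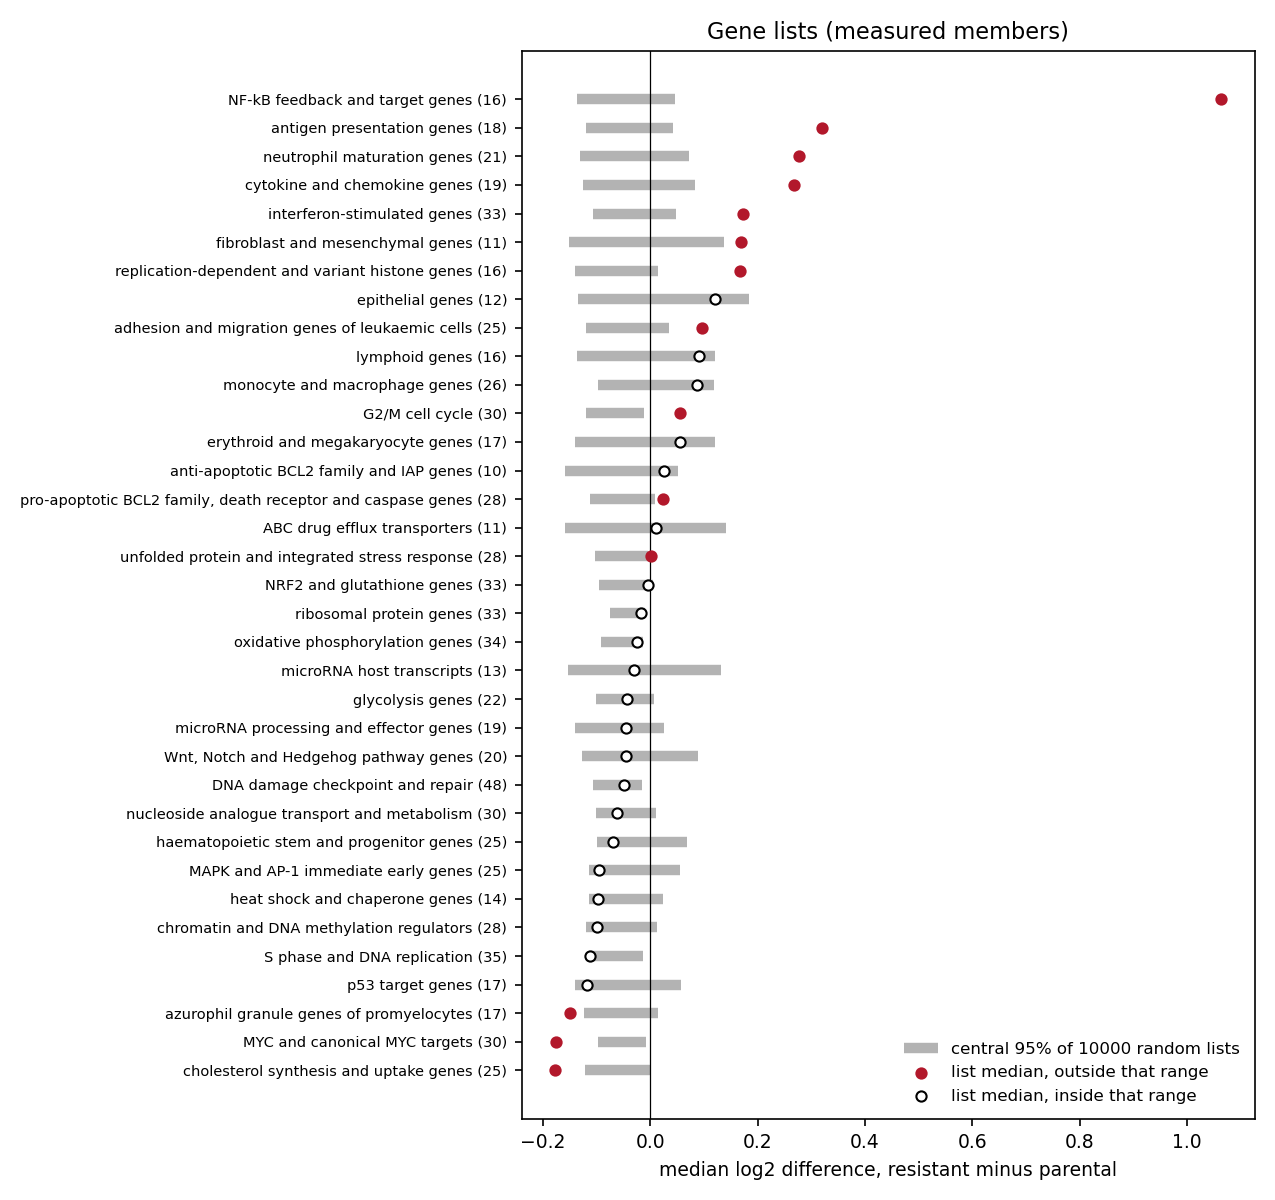
Median log2 difference of each of 35 gene lists (points; number of measured members in parentheses) with the central 95% of medians of 10000 random lists of the same size and brightness (grey bars). Filled points mark the 14 lists outside that range, 11 above and 3 below, with the NF-kB list at 1.06.

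In all, 14 of the 35 lists lay outside the central 95%, where lists of unrelated genes would give 1.75. Members of a list can vary together and some lists share genes, which the random lists leave out. The 14 therefore cannot be read as an excess over chance. Over the main and 14 other settings, 1 of which took means, values ran from 0.16 to 0.46 for neutrophil maturation, 0.21 to 0.62 for cytokines, -0.66 to -0.09 for azurophil granules and -0.18 to -0.11 for MYC targets. Markers of other cell types were among those examined: the fibroblast list had a median of 0.17 at percentile 98.8 over 11 members, with none of the 10 measured on both arrays past 2-fold and COL5A1 at 0.76, and was outside in only 6 of 14 other settings. The lymphoid list (median 0.09, percentile 94.4, CD79B at 0.67, CD3D at 0.65 and LCK at -0.74) and the epithelial list (0.12, percentile 90.4, KRT19 at 0.78) lay inside, but 2 of 14 other settings put the lymphoid list outside. Stem and progenitor genes had a median of -0.07 (percentile 10.1), with CD38 2.76-fold higher, CD34 close to the floor and KIT below it on both arrays. Erythroid and megakaryocyte genes had a median of 0.06 (percentile 86.8), with SLC4A1 2.04-fold higher on its brightest probe and another at 0.12.

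The other lists lay inside, and only HDAC9 among their members was counted as past 2-fold. Medians were -0.12 for p53 targets (percentile 6.51), -0.00 for NRF2 and glutathione genes (percentile 94.8), -0.04 for glycolysis (percentile 49.4), -0.02 for oxidative phosphorylation (percentile 90.9) and -0.02 for ribosomal protein genes (percentile 92.1). They were -0.10 for immediate early genes (percentile 5.84), -0.05 for Wnt, Notch and Hedgehog genes (percentile 35.1) and -0.10 for heat shock genes (percentile 5.99). The median was -0.10 for chromatin regulators (percentile 8.34), where HDAC9 was 2.34-fold lower on 1 of its measured probes and -0.22 on another. The largest differences were those of BTG2 (0.88, p53 targets), GPX2 (0.59, NRF2 and glutathione), SLC2A1 (-0.39, glycolysis), TFAM (-0.26, oxidative phosphorylation) and RPS6 (-0.12, ribosomal). Those of further lists were FOSL1 (-0.91, immediate early), HSPA1B (-0.84, heat shock) and PTCH1 (-0.42, Hedgehog), whose other probes ran from -0.22 to 0.21. The mean of the p53 list was -0.01. MicroRNA processing genes had a median of -0.04 (percentile 62.7), with DGCR8 at -0.33, and microRNA host transcripts a median of -0.03 (percentile 45.4), with H19 at -0.48. Of the lists inside, the immediate early genes were outside in 4 of 14 other settings, the monocyte and the NRF2 lists in 2 each, and the anti-apoptotic and heat shock lists in 1 each.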

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

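The settings with both arrays at or above the 75th percentile, with protein-coding genes only, with loess and the floor at the 60th percentile together, with genes past 2-fold left out of the lists and with eosinophil genes left out of the azurophil list were chosen after seeing the data. The count of 255 genes past 2-fold depended on the floor and the threshold. It was 455 (346 higher, 109 lower) with the floor at the 40th percentile, 152 (102 higher) at the 60th, 150 (102 higher) at the 60th with loess, and 3836 (2536 higher, 1300 lower) with no floor, where dim probes enter and the SD of differences was 0.58 in place of 0.29. It was 1155 (831 higher, 324 lower) at 1.5-fold, 74 (45 higher, 29 lower) at 3-fold, 142 (96 higher, 46 lower) over protein-coding genes and 49 (36 higher, 13 lower) over the brightest genes, as fewer or more genes could pass. An offset of 50 units, which shrinks differences of dim genes, left 106 (66 higher, 40 lower), and the higher share went from 72.5% to 62.3%. The other scalings, the authors' table and the mean of all probes kept the counts within 1.5 times, and no named gene past 2-fold changed sign. Of the lists outside the central 95%, the median of the fibroblast list turned from 0.170 to -0.0334 with no floor, where members below the floor enter. With genes past 2-fold left out, that of the pro-apoptotic list turned from 0.0242 to -0.0126 and that of the unfolded protein list from 0.000837 to -0.00736. Each of these lists had 2 members past 2-fold, higher in both cases, so leaving them out lowers a median that was already close to 0. The offset made the fold of 24 of the 55 named genes past 2-fold smaller by over 1.5 times, bounds included. Of 55 named genes past 2-fold, 40 stayed past it in the same direction under every setting of values or floor. The 15 others were BMF, VCAM1, HLA-F, ATF3, PANTR1, CLPSL1, HDAC9, PRUNE2, SLC4A1, EXOC3L4, KLK3, NALF2, DLG3, TCAM1P and MIR3667HG. For genes above the floor on 1 array, such as VCAM1 and CLPSL1, these values are bounds, and a lower bound that is smaller does not show a smaller difference. Of the 14 lists outside the central 95%, 9 were outside in all 14 other settings. These settings are not independent. The median shift leaves list percentiles unchanged, and the authors' table nearly repeats quantile normalization. Signal over background limits dim genes, since no detection flags were at hand. No paired analysis was possible because each line had 1 array and the labels give no replicate numbers, and for the same reason no array could be left out.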

Other observations

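For the NF-kB list, the tests over bright members and over markers of other cell types were chosen after the result was seen, as were the test of higher against lower counts among bright genes and, for the run on chromosome 18, its limits, the other scalings, the window medians, the protein-coding genes and the gene spacing.

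Genes at the end of chromosome 18 were higher together on the resistant array. In the gene order of assembly GRCh38.p14, 78 measured genes from SMAD2 to PARD6G-AS1 had a median log2 difference of 0.25, or 1.19-fold, and 70 of them lay above the median of the other chromosomes (-0.05). The other 109 measured genes of chromosome 18 had a median of -0.07. Genes past 2-fold are left out of both comparison medians. The limits of the run were set to give the largest summed difference for its length, so these contrasts partly follow from that choice. The run holds the TGF-beta signalling genes SMAD2 (0.31), SMAD4 (0.31) and SMAD7 (0.96), the apoptosis genes BCL2 (0.20) and PMAIP1 (0.99), and MALT1 (0.52), which encodes a paracaspase of NF-kB signalling. A single gene of the run, LINC00908 (1.31), was past 2-fold.

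A gain of this segment in the resistant line may underlie the run. With genes past 2-fold left out, the highest mean over 25 neighbouring genes was 0.33 (SMAD2 to WDR7). The highest of 1000 random gene orders was 0.23. With all genes kept, 0.33 lay inside the random range, whose highest value was 0.52. The condition set beforehand for a copy number change asked for both forms to lie outside, so it was not met. The highest window median, again with all genes kept, was 0.37 against 0.31, and the 24 windows above were all on chromosome 18. Scaling between the arrays is argued against for the form with genes past 2-fold left out, the only form run for other scalings. The highest window lay on chromosome 18 and above its random range under all 4, with 0.34 as the lowest of these means. Of the 4, the median shift moves all genes alike and the authors' table nearly repeats quantile normalization, so these add little. All 4 moved the median difference of genes above the floor only from -0.03 to between -0.02 and -0.00. They therefore had little room to change a window mean of 0.33. Wide spacing of genes is argued against too, since in the same form 1174 windows elsewhere with genes as widely spaced reached at most 0.20. Copy number and shared regulation of the region cannot be told apart, because no DNA was measured here, and some windows on chromosome 4 and, under other scalings, on chromosome 6 also exceeded the random range.

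The higher NF-kB list may reflect a difference between the cultured lines, as a hypothesis, since the technical explanations tested were argued against. Under 4 other scalings of the arrays the list median stayed at 1.07 or more. The median shift adds the same constant to all genes and cannot change a list against its random lists. The authors' table nearly repeats quantile normalization, so the 4 scalings are not separate tests. All 4 moved the median difference of genes above the floor only from -0.03 to between -0.02 and -0.00. They therefore had little room to change a list median of 1.06. Noise of dim probes is argued against, since 5 of the 11 members at or above the 75th percentile of both arrays were past 2-fold higher, against at most 2 in 10000 random sets of 11 such bright genes. The fibroblast list lay above its random range (0.17, percentile 98.8) and CD3D went from 3923 to 6201 and CD79B from 203 to 324, but lymphoid, epithelial or fibroblast cells are argued against as the source, since of 38 of their markers below the parental floor, among them COL1A1, KRT5 and CD3G, the brightest on the resistant array, DCN, reached only 37.7, while RELB went from 4885 to 20352. A share of such cells too small to show in these markers, myeloid cells of other kinds and differences in culture or hybridisation stay open, because each line had 1 array.

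More genes were past 2-fold higher than lower on the resistant array, 185 against 70. Noise of dim probes may add to the counts but is argued against as the whole cause, since among genes with both arrays at or above the 75th percentile 36 were higher and 13 lower, a ratio of 2.77. Over genes measured on both arrays, the median difference ran from 0.04 in the dimmest bin (51 higher, 10 lower) to -0.06 in the brightest (8 higher, 3 lower). The excess was thus largest among dim genes. Loess by brightness, which takes out such a trend, still gave 176 higher and 73 lower. No biological explanation was tested for this excess.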
